A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

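RNA abundance was measured on 1-colour Affymetrix yeast arrays in 12 chemostat cultures of Saccharomyces cerevisiae, 1 array per culture. The design crossed the strain (the prototrophic reference CEN.PK113.7D or the sfp1 null mutant CEN.PK111.32D) with the growth condition (ethanol limitation with air, or glucose limitation without oxygen), with 3 independent cultures in each of the 4 groups. Groups and replicate numbers were taken from the sample titles, which do not say what arrays of the same number share. Deviations from the group mean of same-numbered reference arrays correlated between the conditions (r = 0.281, 0.239 and 0.123 across genes), so the numbers were taken to pair the reference arrays, on the evidence of the data and not of the labels. With 3 arrays per group such a match can arise by chance, so the pairing is not established. In every other pair of groups at least 1 of the 3 correlations was below 0.1, though reference and mutant ethanol arrays came near, with 0.073, 0.129 and 0.119. The label text gave a temperature of 30 °C and a culture pH of 5.0 for the cultures. Total RNA was labelled with the array maker's one-cycle protocol, per the labels.

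The deposited values were linear signal intensity per probe set, computed by the authors in GCOS, the array maker's software, per the submitters' processing notes. The version and settings of GCOS were not given in the sources used here. The 2% trimmed mean of the 9335 probe sets averaged 150.14 and differed by 0.019% between the lowest and the highest array. The arrays were therefore taken as already scaled by the authors, and the intensity values were used as deposited, without further normalization. Global scaling of this kind sets the mean signal of every array to the same value, so it cannot show a change in total messenger RNA per cell. Scanner files and detection calls were not used here, and no scan date or hybridisation batch was given in the sources used here.

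The 60 control probe sets were left out of all tests. A table of the platform's annotation gave 1 gene for 6504 probe sets, several genes for 328 and none for 2443. The 6504 probe sets with 1 gene named 5656 genes, and all of them matched the gene table of assembly R64, with 0 symbols updated. Probe sets of several genes name no gene in the text. For the 315 genes with several probe sets, the one with the highest mean log2 signal stood for the gene. Signal below a floor of 12.0, which is 8% of the trimmed mean, was set to the floor, and values were then taken as log2. Genes above the floor on at least 3 of the 12 arrays were tested, which left 5321. Where every array of 1 group lay at the floor, the fold change is a lower bound and is given as such.

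Differences were tested with limma 3.58.1 in R 4.3.3 by fitting 1 mean per group over all 12 arrays, so that the 4 groups shared 1 estimate of the spread per gene, and with the variance trend of eBayes. The contrasts were mutant minus reference in each condition, the difference of those 2 effects (glucose minus ethanol), and glucose minus ethanol within each strain. P-values were adjusted by the Benjamini-Hochberg method over the 5321 genes, and a gene was called at an adjusted p under 0.05. Unless stated otherwise, fold changes are on the log2 scale with the standard error (SE) from limma, and levels are mean signal with the standard deviation (SD) of 3 arrays. Arrays have no counting depth. The number of arrays and the floor limit the precision, and the median SE of a log2 fold change was 0.21 in a comparison of 2 groups and 0.30 for the difference of effects.

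Gene lists were written from general knowledge, so they need not match published sets of the same name, and were fixed before the data were examined. They covered cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III and their factors, translation factors, aminoacyl-tRNA synthetases, mitochondrial ribosomal proteins, regulators of ribosomal gene transcription, glycolysis and fermentation, gluconeogenesis with the glyoxylate cycle and C2 use, the TCA cycle, the respiratory chain and ATP synthase, fatty acid beta-oxidation and peroxisomes, trehalose and glycogen metabolism, hexose transporters, anaerobic and hypoxic genes, the seripauperin (PAU) family, ergosterol synthesis, the environmental stress response, the proteasome, leucine and branched-chain amino acid synthesis, other amino acid synthesis, methionine and sulfur assimilation, purine synthesis and one-carbon metabolism, the phosphate regulon, the iron regulon, the cell wall, G1 cell cycle and cell size control, mating genes, sporulation genes, and 2 comparison lists (RNA polymerase II with its general factors, and the vacuolar ATPase with actin). Each list was tested with camera at its preset correlation between genes, again with a correlation estimated from the data, and with fry, and p-values were adjusted over the 31 lists within a contrast. Camera compares a list with all other genes, and fry asks whether the genes of a list move, on balance, one way. Members were also counted at adjusted p under 0.05 over all genes and adjusted over the list alone. Of the 137 cytosolic ribosomal protein genes only 80 had a probe set of their own, because 54 shared all of theirs with a paralog. The PAU family had 10 of 24. The purine and one-carbon list also held URA genes of pyrimidine synthesis.

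The genes named in the text were chosen by a rule set before the data were examined. For each strain comparison it took SFP1 and LEU2, and the 10 largest rises and 10 largest falls among called genes whose 3 mutant arrays all lay on one side of the 3 reference arrays and whose higher group mean was at least 4 times the floor. For the difference of effects and for the condition contrasts it took the 5 largest in each direction. In each list it took up to 4 called members with the smallest adjusted p, or up to 2 members of highest signal where none was called. Any other gene in the text is said to have been chosen after its values were seen.

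The procedure was tested on simulated data in which the real standard deviations were shuffled among genes and the noise was independent between genes. Only genes with a mean level above 4 times the floor were changed. The shares recovered therefore do not carry over to weaker genes or to genes that move together. With 200 of 5321 genes changed in the simulated ethanol comparison, the procedure recovered 6.0% of the changes of 1.41-fold, 70.1% of those of 2-fold and 100.0% of those of 4-fold, and 5.6% of its calls were false. It called 0 genes in the simulated glucose comparison without change. Alternatives planned before the data were examined were quantile normalization, median centring, other floors and filters, other variance settings, a fit on only the arrays compared, the replicate number as a block, other rules for several probe sets, stricter thresholds, other list tests, and leaving out each array in turn. Shared ribosomal protein probe sets, a fit on protein-coding genes only and a block on the reference arrays alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9.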

Results

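SFP1 encodes a zinc-finger transcription factor that controls genes for ribosomal proteins and ribosome biogenesis in budding yeast. The study compared the reference strain CEN.PK113.7D with an sfp1 null mutant, CEN.PK111.32D, in chemostats, in which the dilution rate sets the growth rate, so that both strains of a pair grew equally fast. Ethanol-limited cultures were aerated and ran at 0.10 per hour, and glucose-limited cultures were kept without oxygen and ran at 0.05 per hour. Each of the 4 groups had 3 independent cultures and 3 arrays. The median signal of an array was 40.1 to 46.1, and 26.48% to 32.64% of probe sets lay below the floor. Pearson's r between replicate arrays on the log2 scale across genes, which are not independent replicates, was 0.950 to 0.991. Some values between the strains within a condition lay in this range. Reference glucose array 2 had 0.972 with mutant glucose array 3 and 0.950 with reference glucose array 1. Reference glucose replicate 1 differed from the other arrays in its actin controls, with a ratio of the 3' to the 5' probe set of 17.55 against 1.06 to 1.49 elsewhere. The 3' probe sets of 4 spiked poly(A) transcripts read 0.3 to 7.4 on the 3 reference glucose arrays and 13.5 to 357.4 on the other 9, while the 3' probe sets of the hybridisation controls had medians of 248.2 to 550.3 on all 12. Whether the reference glucose arrays were processed apart is not known. Separate processing would enter the strain comparison in glucose, the difference of effects and the condition contrast in the reference. It could not be told there from a strain or condition effect.

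SFP1 (YLR403W) was at the floor on all 6 mutant arrays. In ethanol-limited cultures its signal was 76.6 ± 6.2 (SD, n = 3) in the reference and 1.0 ± 0.7 in the mutant, a difference of at least 6.36-fold (limma adjusted p = 2.72e-05). In glucose-limited cultures it was 102.0 ± 31.3 in the reference and 0.8 ± 0.6 in the mutant, at least 8.18-fold lower (adjusted p = 2.51e-06). LEU2 (YCL018W), which encodes beta-isopropylmalate dehydrogenase, is mutated in the background of the sfp1 strain, where a LEU2 gene of Kluyveromyces lactis replaced SFP1. Its signal fell in ethanol from 1084.2 ± 139.1 to 347.0 ± 79.7, a log2 change of -1.66 ± 0.19 (SE; adjusted p = 0.000308). In glucose it was 1633.1 ± 183.3 and 1374.3 ± 267.4, a log2 change of -0.26 that did not pass the test (adjusted p = 0.397). The LEU2 effect differed between the conditions by 1.40 ± 0.27 (adjusted p = 0.00898). Whether the LEU2 probe sets also detect the Kluyveromyces lactis gene was not tested. Weaker LEU2 probe sets had log2 changes of 0.65 and -0.175 in glucose, and differences between the conditions of 2.44 and 1.31. With the mean of its probe sets the difference was 1.72 and did not pass (adjusted p = 0.0533).

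**Figure D1:**
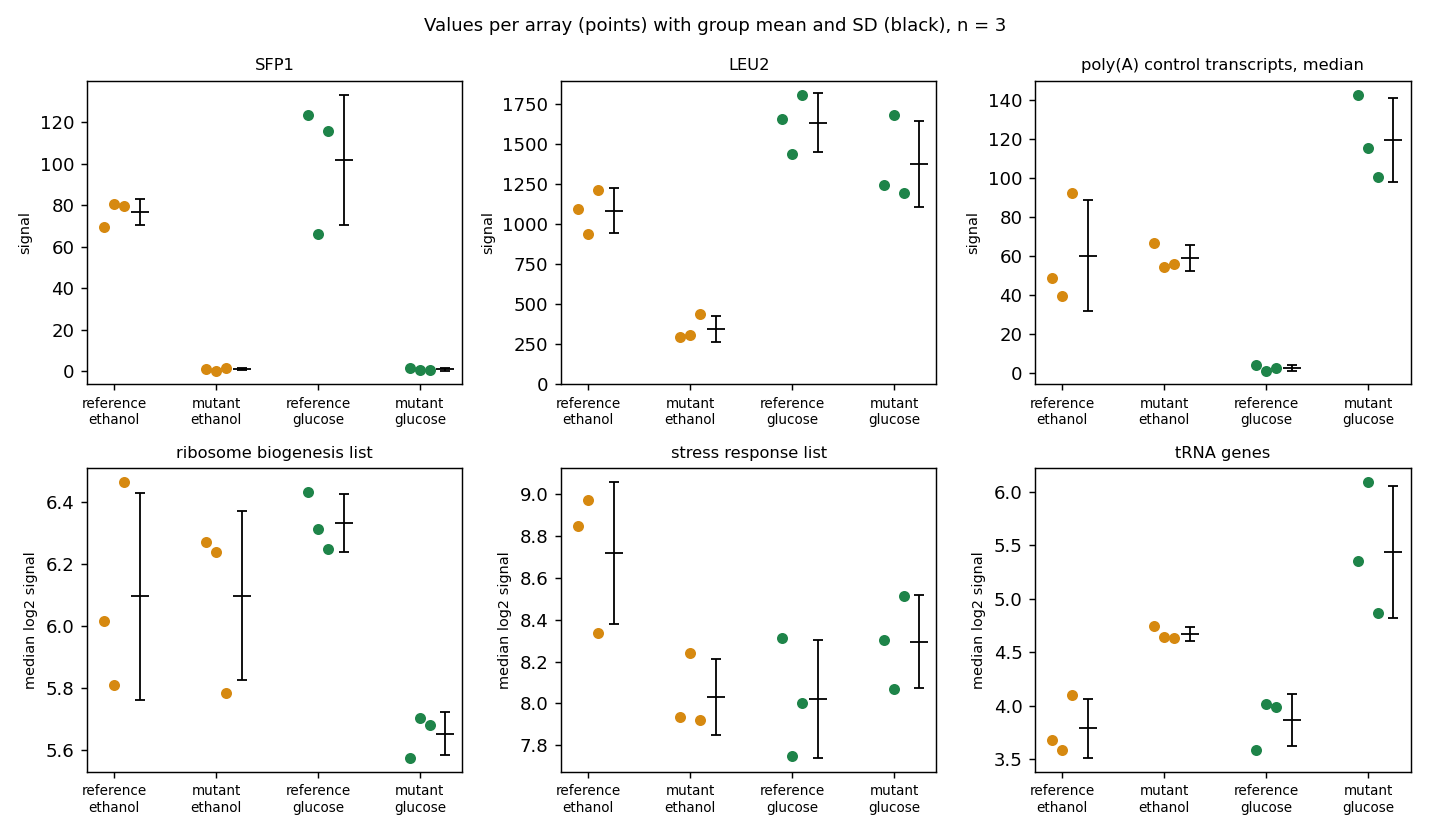
Signal of SFP1, LEU2 and the median of the 3' probe sets of 4 spiked poly(A) transcripts (linear scale), and median log2 signal of the ribosome biogenesis, stress response and tRNA genes, in each of the 12 arrays (points) with the group mean and SD (black, n = 3). SFP1 lay at 0.2 to 1.5 on the 6 mutant arrays, and the ribosome biogenesis median was 5.57 to 5.70 on the 3 mutant glucose arrays against 6.25 to 6.43 on the 3 reference glucose arrays.

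The first question was which transcripts differed between the strains in aerobic, ethanol-limited cultures. The mutant also differed from the reference in LEU2, so no strain comparison here can separate that from the loss of SFP1. PTR2, the di- and tripeptide transporter, had the largest rise once values were set to the floor, from 43.4 ± 8.1 to 451.6 ± 62.1 (SD, n = 3), or 10.5-fold. The glycerol-3-phosphate phosphatase GPP2 rose 4.55-fold, the weak-acid exporter PDR12 3.15-fold, the GTPase RAS1 3.08-fold and the maltose permease MPH2 2.76-fold. YGP1, a secreted glycoprotein, fell from 727.1 ± 260.0 to 86.3 ± 23.5, or 8.24-fold. PMA2, a minor plasma membrane proton ATPase, fell 5.70-fold, the cell wall mannoprotein HPF1 5.22-fold, the ubiquitin-binding protein DSK2 4.68-fold and the water channel AQY1 3.89-fold.

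In total 199 of 5321 genes passed the test in ethanol, 87 of them higher in the mutant and the others lower, and 102 of them (36 higher, 66 lower) differed by at least 2-fold. An unadjusted p under 0.05 was reached by 1031 genes. In 1442 genes the 3 mutant arrays did not overlap the 3 reference arrays, which chance gives for 10% of genes. The other large rises were in PRM10 (log2 1.65 ± 0.25 SE), MFA1 (1.62 ± 0.16), BAR1 (1.51 ± 0.15), RMD6 (1.38 ± 0.26) and MF(ALPHA)1, which was at the floor in the reference and at least 4.69-fold higher in the mutant. The other large falls were in FMP45 (-2.12 ± 0.49), RPL22B (-2.05 ± 0.26), SPG1 (-1.94 ± 0.36) and the elongation factor 3 paralog HEF3 (-1.85 ± 0.29). Over these 19 named genes adjusted p ran from 3.63e-05 for PTR2 to 0.0281 for FMP45. The count fell to 72 without reference ethanol array 1, 87 without reference array 2 and 116 without mutant array 1 or 2, and to 73 when only the 6 ethanol arrays were fitted. FMP45 did not pass without reference array 1 (adjusted p = 0.109) or 2 (0.132) or without mutant array 1 (0.0806), 2 (0.065) or 3 (0.0854), and RMD6 (0.0608) and SPG1 (0.0517) did not without reference array 1. GPP2, PDR12, PRM10, PMA2, FMP45, RPL22B, SPG1 and HEF3 did not pass on the 6 ethanol arrays alone (0.0502 to 0.12), FMP45 did not without the filter on low signal (0.0858), and RMD6 did not with the mean of its probe sets (0.0838). After median centring, 59 rose and 159 fell, a higher share of 27.1% against 43.7%.

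Of 25 measured genes of the mating system 9 rose in ethanol and 0 fell (12 rose adjusted over the list alone), with a median log2 fold change of 0.58. Members with the smallest p were MF(ALPHA)1, the a-factor gene MFA1 (708.8 ± 48.5 to 2189.8 ± 275.8), BAR1, the protease that degrades alpha-factor (131.3 ± 18.0 to 372.3 ± 34.8), and the agglutinin subunit AGA2 (2.12-fold). Camera gave adjusted p = 5.46e-09, and adjusted p = 0.0574 with an estimated correlation. Cell wall genes rose by a median of 0.25, with 6 of 34 higher and 0 lower (9 higher adjusted over the list alone), among them the glucanases SCW10 (1.84-fold) and EXG1 (1.69-fold), the cross-linking enzyme UTR2 (2.34-fold) and the glucan synthase subunit FKS1 (0.58 ± 0.13 SE on the log2 scale). Camera gave adjusted p = 0.00236 for this list, and adjusted p = 0.323 with an estimated correlation, and the median was 0.163 without reference ethanol array 1.

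Of 47 environmental stress genes 9 fell and 0 rose in the ethanol-limited mutant (18 fell adjusted over the list alone), and the list's median was -0.43, or -0.702 without reference ethanol array 3. The smallest p were those of YGP1, the Hsp70 gene SSA3 (-1.50 ± 0.28 SE), the small heat shock protein HSP26 (-1.16 ± 0.22) and the mitochondrial superoxide dismutase SOD2 (-1.06 ± 0.20). Camera gave adjusted p = 8.48e-12, and adjusted p = 0.326 with an estimated correlation. Trehalose and glycogen genes had a median of -0.28 (-0.629 without reference array 3) and 1 of 21 fell, the trehalase ATH1 (-0.75 ± 0.19; 2 fell adjusted over the list alone). Their camera adjusted p = 0.0123 became adjusted p = 0.773 with an estimated correlation. In glycolysis and fermentation the enolase ENO1 fell from 3544.0 ± 298.0 to 1177.1 ± 113.3 and the hexokinase HXK1 fell 2.03-fold, while GPP2 rose. That is 1 higher and 2 lower of 28 (1 and 6 adjusted over the list alone), with a median of -0.16 and a camera adjusted p = 0.0177, and adjusted p = 0.323 with an estimated correlation. In ergosterol synthesis 1 of 25 fell, ERG28 (1.75-fold; 5 fell and 1 rose adjusted over the list alone), with a median of -0.18 and a camera adjusted p = 0.0175, and adjusted p = 0.323 with an estimated correlation. Leaving out mutant ethanol array 3 ended the ergosterol (median -0.115), cell wall and trehalose calls (adjusted p = 0.0617 in each). The trehalose call also ended without reference array 1 (0.0598) or 2 (0.166), and the glycolysis call without reference array 2 (median -0.093, adjusted p = 0.0521) or mutant array 2 (0.0551) and with the floor at 20% of the trimmed mean (0.053). Without reference array 2 the ergosterol median was -0.276. Fry did not call the trehalose list (0.353).

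The genes that SFP1 is best known for moved little in ethanol. Of 156 ribosome biogenesis genes 0 rose and 2 fell (0 adjusted over the list alone), NOP8 (-1.35 ± 0.30 SE) and RCL1 (-0.97 ± 0.25), and the list's median was -0.01 (camera adjusted p = 0.482). Without reference ethanol array 3 that median was 0.214 (adjusted p = 0.00817), and without reference array 2 it was -0.163 (adjusted p = 0.000332). Of 80 cytosolic ribosomal protein genes RPS28B and RPS10B rose 1.75-fold and 1.52-fold, and RPL22B and RPL7B fell 4.14-fold and 2.53-fold (2 rose and 3 fell adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.144), and camera passed after quantile normalization (adjusted p = 0.0388) and without reference array 3 (1.96e-05) or mutant array 2 (0.0396). With 59 shared ribosomal protein probe sets added, an alternative chosen after seeing the data, 2 rose and 4 fell. RNA polymerase I and III genes had 1 called member of 35, RPA14 (-1.66 ± 0.37), with a median of 0.07 and a mean of -0.01 (0.823). Among translation factors the initiation factor subunit RPG1 fell 1.73-fold (median -0.16, camera adjusted p = 0.0529), and among aminoacyl-tRNA synthetases GUS1 fell 1.65-fold (median -0.11, 0.0781). In each of these 3 lists 1 fell adjusted over the list alone.

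**Figure D2:**
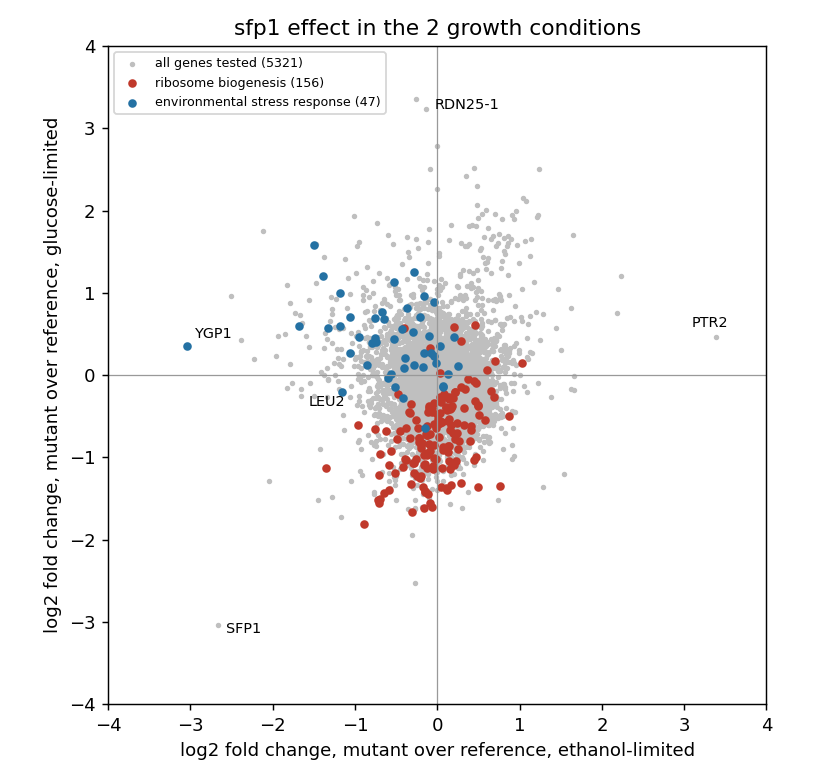
Log2 fold change of mutant over reference in ethanol-limited (horizontal) and glucose-limited (vertical) cultures for the 5321 genes tested, with ribosome biogenesis genes (red, 156) and stress response genes (blue, 47) marked. Ribosome biogenesis genes lie mostly below 0 on the vertical axis (median -0.73) and around 0 on the horizontal one (median -0.01).

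In anaerobic, glucose-limited cultures of the mutant 73 of 156 ribosome biogenesis genes fell and 0 rose (95 fell adjusted over the list alone), with a median log2 fold change of -0.73. The GTPase NOG2, needed for export of the large subunit, fell from 337.3 ± 53.5 to 98.1 ± 24.9 (SD, n = 3), a log2 change of -1.80, while a weaker NOG2 probe set had -0.75 and a difference between the conditions of 0.63, against -0.91 for the one used. PNO1 fell 2.85-fold, the rRNA methyltransferase NOP2 2.84-fold and CIC1 3.06-fold. Camera gave adjusted p = 5.39e-19, and adjusted p = 0.295 with an estimated correlation, and fry gave 0.00981. Fry also called the RNA polymerase II comparison list lower in this contrast (adjusted p = 0.0257). Without reference glucose array 1, the one with the high actin ratio, the median was -0.718.

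Other lists of the translation machinery were tested in glucose as well. Of 38 translation factors 17 fell and 1 rose (22 and 1 adjusted over the list alone), including the initiation factor subunits SUI2 (3.05-fold) and NIP1 (2.58-fold), the elongation factor subunit TEF4 (2.25-fold) and the release factor SUP45 (1.98-fold). A weaker probe set of TEF4 had a log2 change of 0.14. Their median was -0.60 (camera adjusted p = 4.17e-08; adjusted p = 0.137 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases 9 fell (13 adjusted over the list alone), among them MES1, GLN4, SES1 and WRS1, by 1.88-fold to 2.27-fold, and the median was -0.63 (4.69e-06; adjusted p = 0.178 with an estimated correlation). Of 35 genes of RNA polymerase I and III 10 fell (12 adjusted over the list alone), led by the polymerase I subunits RPA43 (3.06-fold), RPA34 (2.80-fold), RPA49 (2.44-fold) and RPA190 (2.72-fold, or -1.44 on the log2 scale, with -0.58 in its second strongest probe set). That list had a median of -0.38 (0.0014; adjusted p = 0.345 with an estimated correlation). Of 80 cytosolic ribosomal protein genes 7 fell and 0 rose (7 adjusted over the list alone), with RPS22B (822.2 ± 86.8 to 319.5 ± 13.6), RPS9A, RPL9B and RPL22B at the smallest p. Their median was 0.00 and their mean -0.08, while camera's direction was up (adjusted p = 0.916), and 12 of 139 fell with the shared probe sets added. Mitochondrial ribosomal proteins had a median of -0.30, with 4 lower (MRPL39, RSM25 and MRPL32 among them) and 2 higher (IMG1 among them) of 70, the same numbers adjusted over the list alone. Camera gave adjusted p = 0.0235 for them, and adjusted p = 0.636 with an estimated correlation, and the call ended without reference array 1 (median -0.168, adjusted p = 0.119), without mutant array 3 (0.0582) and after quantile normalization (0.0803), and fry did not call it (0.053).

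Of the lists for biosynthesis and protein turnover, 4 had a lower median in the glucose-limited mutant and passed camera. In the purine and one-carbon list, which also holds pyrimidine genes, 16 of 40 fell (19 adjusted over the list alone). They included the pyrimidine gene URA5 as well as FCY2, PRS5 and PRS3, each by 1.92-fold to 2.09-fold. The list had a median of -0.39 (camera adjusted p = 0.00809; adjusted p = 0.347 with an estimated correlation), or -0.232 without mutant array 1. In other amino acid synthesis 16 of 54 fell and 1 rose (19 and 1 adjusted over the list alone), with HOM3, ASN1, SER3 and LYS9 at the smallest p and a median of -0.42 (0.000403; adjusted p = 0.178 with an estimated correlation). In ergosterol synthesis 6 of 25 fell (12 adjusted over the list alone), including CYB5 (2.86-fold), ERG5 (2.07-fold), ERG28 (1.76-fold) and ERG27 (1.71-fold), with a median of -0.45 (0.001; adjusted p = 0.137 with an estimated correlation). In the proteasome 5 of 36 fell (5 adjusted over the list alone), with RPN9 (2.68-fold), PRE1, RPN3 and RPN6 at the smallest p and a median of -0.26 (0.0196; adjusted p = 0.603 with an estimated correlation). The proteasome median was -0.438 without reference array 2, and its call ended without reference array 3 (0.0579) or mutant array 1 (0.058).

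Of 34 cell wall genes 11 rose in glucose and 0 fell (15 rose adjusted over the list alone), including the wall proteins SED1 (2.79-fold), CWP1 (2.46-fold) and PIR3 (2.93-fold) and the flocculin FLO11 (990.9 ± 373.1 to 2539.4 ± 313.3, SD, n = 3). Their median was 0.45 (camera adjusted p = 7.23e-12), and this was the only strain effect on a list that kept its call with an estimated correlation (adjusted p = 0.0439). Of 47 stress genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), with SPI1 (2.38-fold), DDR2 (1.76-fold) and the Hsp70 genes SSA3 (51.5 ± 16.1 to 152.4 ± 38.6) and SSA4 (2.19-fold) at the smallest p. The stress median was 0.40 (4.17e-08; adjusted p = 0.297 with an estimated correlation, and 0.053 with fry). Of 10 PAU genes 3 rose, PAU23, PAU17 and PAU13 (5 adjusted over the list alone), with a median of 0.50 (4.26e-05; adjusted p = 0.178 with an estimated correlation). In the TCA cycle 2 of 24 rose, IDH1 (1.81-fold) and KGD1 (1.55-fold), with a median of 0.23 (0.00164; 1 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation). Of 25 mating genes 3 rose, MF(ALPHA)1 (2.31-fold), MFA1 (1.76-fold) and FIG2 (1.98-fold), the same number adjusted over the list alone, with a median of 0.23 (0.00164; adjusted p = 0.178 with an estimated correlation).

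Across all genes 718 of 5321 passed the test in glucose, 242 higher and 476 lower, and 269 (119 higher, 150 lower) differed by at least 2-fold. Separate processing of the reference glucose arrays, if it occurred, would enter these calls. An unadjusted p under 0.05 was reached by 1550 genes, and 1766 had non-overlapping arrays (10% by chance). All 10 of the largest rises were non-coding RNAs: the 25S ribosomal RNA gene RDN25-1 (3.23 ± 0.55 SE), the tRNA genes SUF6, SUF1, YNCK0005C, YNCM0009C, YNCE0012W, YNCJ0023C and YNCD0019C (2.11 to 2.78), the small nucleolar RNA SNR13 (2.42 ± 0.49), and the RNase P RNA RPR1, which was at the floor in the reference and at least 4.79-fold higher in the mutant. The tRNA probe sets named here bear the suffix of gene families, so near-identical copies cannot be told apart. Among 73 tRNA genes 56 rose and 0 fell, and a control probe set for 25S ribosomal RNA read 275.2 to 509.8 on the mutant glucose arrays against 13.8 to 115.7 elsewhere. The largest falls after SFP1 were in SNO1 (-2.53 ± 0.25) and SNZ1 (-1.62 ± 0.18), both of vitamin B6 synthesis, the ammonium permease MEP3 (-1.95 ± 0.34), NOG2 (-1.80 ± 0.24), RFU1 (-1.72 ± 0.35), NOG1 (-1.67 ± 0.31), the arginine methyltransferase HMT1 (-1.63 ± 0.22), RPS9A (3.08-fold) and RPA43 (-1.61 ± 0.24). Adjusted p over these named genes ran from 2.51e-06 for SUF6 to 0.0129 for RPR1. The count was 447, 435 and 459 without mutant glucose array 1, 2 and 3, and 448 when only the 6 glucose arrays were fitted, where SNR13 (adjusted p = 0.0537) and RPR1 (0.115) did not pass. With a floor at 20% of the trimmed mean MEP3 (0.0857) and RFU1 (0.0569) did not, and without the filter on low signal RPR1 did not (0.0512). The log2 change of RPR1 was 1.383 without mutant glucose array 2. A second RDN25-1 probe set, below the floor on average at 8.24, had a change of 0.04. Without reference glucose array 1, left out because of its actin ratio, 487 passed (213 higher, 274 lower).

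The remaining lists did not pass camera in the glucose comparison, though some of their genes changed. In gluconeogenesis and C2 use the isocitrate lyase ICL1 (56.8 ± 1.0 to 128.4 ± 11.5, SD, n = 3), IDP2, MLS1, FBP1 and 1 other of 28 rose and 1 fell (7 and 5 adjusted over the list alone), with a median of -0.01 and a mean of 0.11 (camera adjusted p = 0.0934). In leucine and branched-chain synthesis LEU1 (2.98-fold) and OAC1 (1.53-fold) rose, and LEU9 (2.71-fold), BAT2 (2.01-fold) and 1 other fell (3 and 4 adjusted over the list alone; median 0.14, 0.657). Among anaerobic genes PAU23 and 1 other rose, and ANB1 (2417.0 ± 209.1 to 998.1 ± 148.0), YSR3, OSM1 and 1 other fell (5 and 7 adjusted over the list alone; median -0.08 with camera's direction up, 0.807). In the G1 list the cyclin genes CLN3 (1.98-fold) and PCL1 (1.68-fold) rose and 5 fell, with DSE4 and SCW11 at the smallest p (2 and 5 adjusted over the list alone; median -0.14, 0.916). Among regulators of ribosomal gene transcription MRS6 and ESA1 fell (1 adjusted over the list alone; median -0.13, 0.683), while in ethanol RAS1 and TPK3 rose and CRF1 fell (2 and 2 adjusted over the list alone).

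Smaller changes fell in lists for transport and respiration. The hexose transporters HXT4 and HXT10 rose 2.21-fold and 1.70-fold and GAL2 at least 1.54-fold, all at low signal (3 rose and 1 fell adjusted over the list alone; median 0.18, camera adjusted p = 0.0615). In the iron list FIT1 (2.71-fold) and ISU2 rose and CTH1 fell (2 and 1 adjusted over the list alone; median 0.06, 0.146). In sulfur assimilation STR3 rose and the sulfate permease SUL1 (2.27-fold) and CYS4 fell (2 and 2 adjusted over the list alone; median -0.11, 0.668). In the respiratory chain QCR2, INH1 and CYT1 rose (2 adjusted over the list alone; median 0.02, 0.207). In beta-oxidation PEX2 and POT1 rose and CTA1 fell (the same adjusted over the list alone; median -0.04 with camera's direction up, 0.875). GIT1 of the phosphate list fell (0 adjusted over the list alone; median -0.18, 0.880), as did the sporulation gene SPO20 (1 adjusted over the list alone; median -0.06 with camera's direction up, 0.854). Of glycolysis genes 0 of 28 passed, with TDH3 at 5446.5 ± 785.7 and 7957.6 ± 1360.0 (adjusted p = 0.0919; list median 0.16, 0.0903), and of trehalose genes 0 of 21 (median 0.06, 0.0615). The comparison lists had medians of -0.17 for RNA polymerase II, with TFB1 and TFB4 lower (camera adjusted p = 0.228), and -0.02 for the vacuolar ATPase and actin, with VMA8 and ARC18 lower (0.854), and in each 2 fell adjusted over the list alone.

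**Figure D3:**
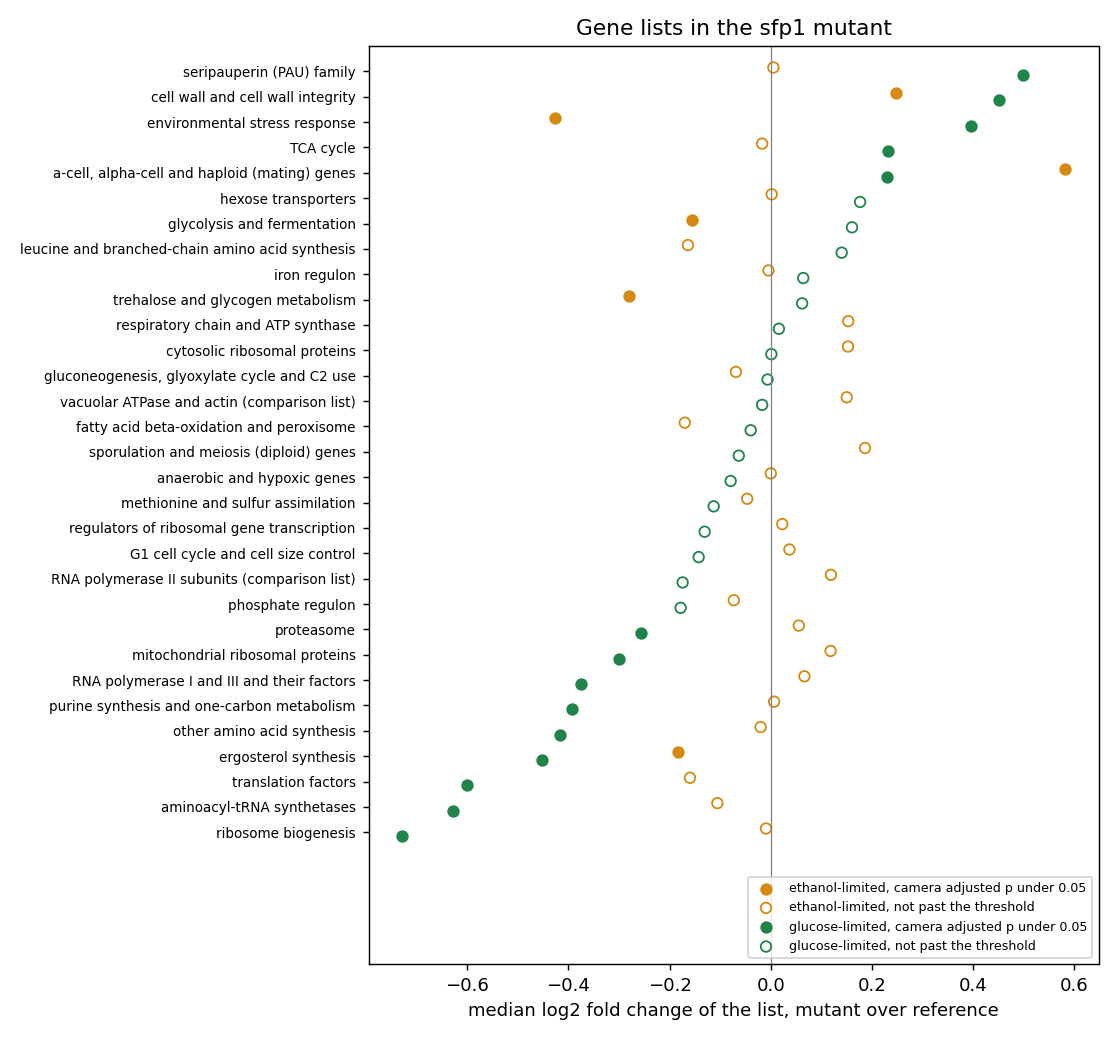
Median log2 fold change of each gene list, mutant over reference, in ethanol-limited (orange) and glucose-limited (green) cultures, with filled points where camera's adjusted p was under 0.05. The stress list lies at -0.43 in ethanol and 0.40 in glucose, and ribosome biogenesis at -0.01 and -0.73.

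Whether the strains differed in another way in each condition was tested as the difference of the 2 strain effects. Stress genes had the largest difference of any list, with a median of 0.96, and 15 of 47 members differed upwards and 0 downwards (28 adjusted over the list alone). YGP1 differed by 3.40 ± 0.39 (SE), SSA3 by 3.08 ± 0.40, SOD2 by 1.77 ± 0.29 and DDR2 by 1.18 ± 0.18. Ribosome biogenesis differed the other way, with a median of -0.71 and 23 of 156 called (40 adjusted over the list alone), among them FCF2, UTP9, CMS1 and NOC2 (by 2.42-fold to 4.33-fold). Camera gave adjusted p = 2.44e-17 for the stress list and 5.02e-11 for ribosome biogenesis, and adjusted p = 0.397 and adjusted p = 0.478 with an estimated correlation.

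In all 436 genes had an effect that differed between the conditions, 179 upwards and 257 downwards, and 338 by at least 2-fold (156 and 182). The reference glucose arrays enter each of these differences, so separate processing of those arrays cannot be told from a differing effect. An unadjusted p under 0.05 was reached by 1431. The largest were FMP45 (3.86 ± 0.69 SE), PMA2 (3.47 ± 0.60), YGP1, RDN25-1 (3.36 ± 0.78) and the transketolase TKL2 (3.10 ± 0.66) upwards, and PTR2 (-2.93 ± 0.42), the acidic amino acid permease DIP5 (-2.74 ± 0.27), YJL213W (-2.64 ± 0.38), SNO1 (-2.26 ± 0.36) and ICY1 (-2.25 ± 0.31) downwards. The count fell to 218 and 193 without reference ethanol array 1 and 2, to 228 and 213 without mutant ethanol array 1 and 2, and to 259, 266 and 268 without mutant glucose array 1, 2 and 3. It was 320 without reference glucose array 1. RDN25-1 did not pass without the filter on low signal (0.0597). Median centring moved the median of all genes from -0.16 to -0.03 and the split to 226 upwards and 143 downwards, a share of 61.2% against 41.1%.

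Other lists with a difference by camera were smaller in size. Translation factors had a median of -0.54 (8 of 38 lower, 12 lower and 1 higher adjusted over the list alone, with SUI2, TIF11, TEF4 and GCD1 at the smallest p; adjusted p = 0.00504, and adjusted p = 0.478 with an estimated correlation). The weaker TEF4 probe set differed by 0.63, opposite to the one used. Aminoacyl-tRNA synthetases had -0.53 (MES1 and GLN4 lower, 3 adjusted over the list alone; 0.0253, and adjusted p = 0.478 with an estimated correlation), and RNA polymerase I and III genes -0.32 (7 of 35 lower, 8 adjusted over the list alone, led by RPA43; 0.0253, and adjusted p = 0.478 with an estimated correlation). Proteasome genes had -0.27 (4 of 36 lower, 5 adjusted over the list alone, led by RPN9; 0.0253, and adjusted p = 0.507 with an estimated correlation). Mitochondrial ribosomal proteins had -0.37 (6 lower, and 1 higher, IMG1, of 70, 8 and 1 adjusted over the list alone; 0.0448, and adjusted p = 0.541 with an estimated correlation). Upwards, glycolysis had 0.18 (ENO1 and ENO2 of 28, 6 higher and 1 lower adjusted over the list alone; 0.00648, and adjusted p = 0.397 with an estimated correlation) and the TCA cycle 0.23 (IDH1, DIC1 and KGD1 of 24, 3 adjusted over the list alone; 0.0184, and adjusted p = 0.397 with an estimated correlation). The PAU family had 0.51 (PAU13 and PAU23 of 10, 3 adjusted over the list alone; 0.00128, and adjusted p = 0.478 with an estimated correlation), trehalose and glycogen 0.49 (PGM2 of 21, 0 adjusted over the list alone; 0.00169, and adjusted p = 0.478 with an estimated correlation) and the cell wall 0.21 (5 of 34 higher and UTR2 lower, 6 and 1 adjusted over the list alone; 0.00671, and adjusted p = 0.478 with an estimated correlation). Leaving out 1 array ended the calls of 4 of these lists: polymerase I and III without mutant ethanol array 1 (0.0712) or mutant glucose array 1 (0.058), the synthetases without reference ethanol array 2 (0.0785) or mutant ethanol array 1 (0.0588), the proteasome without mutant ethanol array 1 (0.0757) or mutant glucose array 1 (0.058), and the mitochondrial list without reference ethanol array 3 (0.169), reference glucose array 1 (0.0839), mutant ethanol array 1 (0.0889) or 3 (0.073), or mutant glucose array 1 (0.0547) or 3 (0.0728). The mitochondrial call also ended after quantile normalization (0.0586), with the floor at 20% of the trimmed mean (0.0528), with a stricter filter on low signal (0.0553) and with protein-coding genes only (0.059). Fry did not call the mitochondrial (0.0592), trehalose (0.223) or cell wall (0.0537) difference. Cytosolic ribosomal proteins had a median difference of -0.15 with 7 of 80 lower (8 adjusted over the list alone; camera adjusted p = 0.347), which passed after quantile normalization (0.0127), without reference ethanol array 3 (0.00703) and without reference glucose array 1 (0.0355).

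Leaving out 1 array also moved some medians of these differences without ending the call, apart from the mitochondrial list. RNA polymerase I and III had -0.544 without mutant ethanol array 3, the proteasome -0.475 without reference glucose array 2, the mitochondrial list -0.245 without reference glucose array 1 and glycolysis 0.278 without reference glucose array 3. The TCA cycle had 0.064 without reference glucose array 2 and 0.353 without reference glucose array 1. The cell wall list had 0.116 without mutant ethanol array 2, 0.13 without reference glucose array 1, 0.324 without mutant ethanol array 3 and 0.33 without reference glucose array 2. The comparison lists had negative medians too, -0.36 for RNA polymerase II (TFB4 lower, 1 adjusted over the list alone; camera adjusted p = 0.117) and -0.13 for the vacuolar ATPase and actin (ARC18 and VMA8 lower, 0 adjusted over the list alone; 0.479), against -0.16 over all genes. Fry gave these 2 lists adjusted p = 0.037 and 0.0392.

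In all 39 genes were called in the same direction in both conditions. The 2 comparisons share no array, but the fit gave them 1 spread per gene, so their calls are not independent. They shared 23 rises, where independent lists of 87 and 242 genes would share 3.96, and these included MFA1, MF(ALPHA)1, CWP1, EXG1, SCW10, MPH2 and PRM10, besides several tRNA genes. They shared 16 falls, SFP1 and RPL22B among them (odds ratio 1.72). Another 14 genes fell in ethanol and rose in glucose, against 5.09 for independent lists, including SSA3, SOD2, FMP45, POT1, YAT1 and PUT4, and 6 rose in ethanol and fell in glucose, against 7.78, including DIP5 and LYS9. With each comparison fitted on its own arrays they shared 10 rises against 1.09 (Fisher's exact test, two-sided p = 6.95e-08), 2 falls against 1.91 (p = 0.717), 1 gene that fell in ethanol and rose in glucose against 0.952 (p = 0.620) and 1 the other way against 2.19 (p = 0.724). Fisher's test takes genes as independent, which they are not, and the 10 rises include tRNA genes such as YNCJ0023C. The 39 shared genes became 16 and 22 without reference ethanol array 1 and 2, 20 without mutant ethanol array 2, and 12 when each comparison was fitted on its own arrays. Across all genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had r = 0.016. The difference itself was called in 68 of the 140 genes called in ethanol alone, 244 of the 659 called in glucose alone and 21 of the 59 called in both, so a call in 1 condition alone does not show a different response.

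The growth conditions differed in carbon source, oxygen and dilution rate together, and their contrast cannot separate these. In the reference, ANB1, the hypoxic form of translation factor 5A, rose from 9.3 ± 3.1 to 2417.0 ± 209.1 (SD, n = 3) under anaerobic glucose limitation, the cell wall mannoprotein gene DAN1 by at least 258-fold, and TIR4 and TIR1 by 65.0-fold and 49.3-fold. Of 33 anaerobic genes 24 rose and 5 fell (24 and 6 adjusted over the list alone), and all 10 PAU genes rose (10 adjusted over the list alone). ADH2, the ethanol-oxidising alcohol dehydrogenase, fell from 6342.6 ± 368.3 to 23.6 ± 6.9, the malate synthase MLS1 165-fold, the gluconeogenic FBP1 128-fold and the proline permease PUT4 178-fold, while the acetate transporter ADY2 fell at least 189-fold. Of 28 genes for gluconeogenesis and C2 use 26 fell and 0 rose (26 adjusted over the list alone), with a median of -3.66.

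Respiratory lists followed in the reference. In the TCA cycle 20 of 24 fell and 2 rose (20 and 3 adjusted over the list alone), with CIT3, IDH1, SDH1 and FUM1 at the smallest p. In the respiratory chain 33 of 48 fell and 4 rose (35 and 4 adjusted over the list alone), with the NADH dehydrogenases NDE1 and NDE2 lower by 6.43-fold and 31.9-fold. In beta-oxidation 22 of 28 fell and 1 rose (25 and 1 adjusted over the list alone), and glycolysis had 14 of 28 higher and 0 lower (14 and 1 adjusted over the list alone), HXK1 6.82-fold. Mating genes had 14 of 25 higher (15 adjusted over the list alone), among them FIG1, BAR1 and MFA1. These lists, the anaerobic and PAU lists and gluconeogenesis passed camera with preset and with estimated correlation in both strains. With the replicate number as a block, glycolysis, the respiratory chain and the PAU family in the reference did not pass with an estimated correlation (adjusted p = 0.0766, 0.0948 and 0.0672). Altogether 1783 genes passed the test in the reference, 843 higher and 940 lower, 791 of them by at least 2-fold (325 and 466), and 2414 had non-overlapping arrays (10% by chance). Separate processing of the reference glucose arrays, if it occurred, would enter this count too. DIP5 rose 79.6-fold and was among the 5 largest rises.

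In the mutant 1684 genes passed, 553 higher and 1131 lower (median centring gave 682 and 864, a share of 44.1% against 32.8%, and moved the median of all genes from -0.18 to -0.06), and 702 differed by at least 2-fold (301 and 401). The largest were DAN1 (at least 295-fold), TIR4, FLO11, ANB1 and TIR1 upwards and ADH2, ADY2, MLS1, the succinate-fumarate transporter SFC1 and the carnitine carrier CRC1 downwards. FLO11 went from 28.3 ± 4.2 to 2539.4 ± 313.3 (SD, n = 3) in the mutant and from 36.3 ± 8.6 to 990.9 ± 373.1 in the reference. Gluconeogenesis had 25 of 28 lower (26 adjusted over the list alone), anaerobic genes 25 of 33 higher and 4 lower (25 and 4), and glycolysis 19 of 28 higher (20 higher and 1 lower adjusted over the list alone). Ribosome biogenesis went up with the condition in the reference (37 of 156 higher, 2 lower, 32 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 7.27e-05, adjusted p = 0.646 with an estimated correlation) and down in the mutant (28 lower, 1 higher, 20 and 0 adjusted over the list alone; -0.35, 0.0394, adjusted p = 0.900 with an estimated correlation). Stress genes went down in the reference (22 of 47 lower, 5 higher, 24 and 7 adjusted over the list alone; -0.58, 0.000478, adjusted p = 0.646 with an estimated correlation) and up in the mutant (13 higher, 4 lower, 13 and 4 adjusted over the list alone; 0.16, 0.000845, adjusted p = 0.564 with an estimated correlation). Fry called neither ribosome biogenesis change (adjusted p = 0.119 in the reference and 0.0954 in the mutant). It called the stress fall in the reference (0.0102) but not the stress rise in the mutant (0.089). Proteasome genes had 24 of 36 lower in the mutant (29 adjusted over the list alone; adjusted p = 3.7e-06, and adjusted p = 0.234 with an estimated correlation) and 8 lower and 1 higher in the reference (8 and 1; 0.026, adjusted p = 0.646 with an estimated correlation). Translation factors passed camera for the condition in the reference (10 of 38 higher and 3 lower, the same adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.584 with an estimated correlation) and did not in the mutant (0.741). In the reference TEF4 rose 2.33-fold, while its weaker probe set had a log2 change of -0.73.

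Another 5 lists passed camera for the condition in the mutant and did not in the reference, which by itself is no difference between the strains. By camera's test of that difference trehalose and the cell wall passed, as given above, and other amino acid synthesis (adjusted p = 0.0535), leucine and branched-chain synthesis (0.147) and the hexose transporters (0.314) did not. Trehalose and glycogen genes had 8 of 21 higher and 3 lower, with GPH1 (6.59-fold) and GSY1 (3.86-fold) at the smallest p (12 and 3 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.492 with an estimated correlation). In other amino acid synthesis 22 of 54 were lower and 3 higher, including ARO9 (24.4-fold) and LYS9 (2.93-fold) among the falls (28 and 4 adjusted over the list alone; 0.0103, and adjusted p = 0.270 with an estimated correlation). Leucine and branched-chain genes had 6 of 14 higher and BAT2 lower (7 and 2 adjusted over the list alone; 0.016, and adjusted p = 0.0732 with an estimated correlation). Cell wall genes had 6 of 34 higher and 3 lower (the same adjusted over the list alone; 0.00905, and adjusted p = 0.236 with an estimated correlation). Hexose transporters had 6 of 14 higher and 2 lower (7 and 2 adjusted over the list alone; 0.0464, and adjusted p = 0.134 with an estimated correlation).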

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

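The regrouping of the arrays was set before the data were seen, except for the one that keeps pairs together. The other tests of technical explanations were chosen only after the result was seen, although the repeats with other scalings and without 1 array that they use had been planned. Results are given here because the strain effect differed between the conditions, or because a signal lay in probe sets that no comparison used. The difference was judged by the limma test for genes, and for lists by both camera at its preset correlation and fry. Groups of 3 arrays are too small for a test of a single far array, so none was applied.

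The number of genes whose effect differed between the conditions was 436. When the strain labels were exchanged within both conditions, 1 of 100 drawn groupings, the real one, reached that count, and the highest of the others gave 222. That grouping kept the true glucose groups and exchanged only reference ethanol array 3 with mutant ethanol array 3. These groupings ignored the possible pairing of the reference arrays. Of all 28 groupings that gave same-numbered reference arrays the same strain label, only the real one reached the count, with 0 as the highest of the others. Those others all mixed the strains in both conditions, which puts any strain effect into the spread, so no conclusion is drawn from their 0. Many of the 100 drawn groupings mixed the strains in both conditions too, so the gap to their low counts carries the same limit. That the real grouping ranked first of 100 speaks only against strain labels that make no difference at all. Exchanging labels asks whether the strain matters at all, so it cannot show that the effects differ between the conditions. For the comparisons of 2 groups only 10 groupings exist, too few for a share under 0.05. The real grouping was the only 1 of 10 to reach its count in each, with 199 calls in ethanol (highest other 0), 718 in glucose (0), 1783 for the condition in the reference (1) and 1684 for the condition in the mutant (0). Of the 4 groupings that part all same-numbered reference arrays, the other 3 gave 0 calls. In comparisons of 2 groups every other grouping mixed the groups, which puts any real effect into the spread. No conclusion is drawn from those low counts.

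In glucose 64 of 109 non-coding genes rose in the mutant and 5 fell, with RDN25-1 differing between the conditions by 3.36, SUF6 by 2.78, SUF1 by 2.59, YNCK0005C by 2.07 and YNCE0012W by 1.82. More RNA without a poly(A) tail in the labelled material of the mutant glucose arrays would raise them together with ribosomal RNA. The 10 ribosomal RNA control probe sets were higher there by a median of 1.68, taken without the floor set for genes. Many of their values lay below that floor, so the size of 1.68 rests partly on weak signal. Only 5 of them read higher on all 3 mutant glucose arrays than on every other array. For an 18S control that was 8.9 against 8.7, below the floor, while a 25S control read 275.2 or more against 115.7 at most. Of 27 small nucleolar RNAs, which also lack a poly(A) tail, 2 rose and 4 fell (median 0.17), and in ethanol 9 of 73 tRNA genes rose and 0 fell (median 0.54), so this explanation stays open. Separate processing of the reference glucose arrays, where the 3' probe sets of 4 spiked poly(A) transcripts read 7.4 at most, would have set these apart from the reference ethanol arrays, but the non-coding genes differed by only 0.03, and a real difference of the conditions could hide such a shift, so it stays open too. Loss of SFP1 raising these RNAs in cells was not tested apart from this and also remains open.

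Of 156 ribosome biogenesis genes 73 fell in the mutant in glucose, and the list differed between the conditions by -0.71 (adjusted p = 0.295 with an estimated correlation in glucose and adjusted p = 0.478 with an estimated correlation for the difference). Degraded RNA in reference glucose replicate 1, whose actin ratio was 17.55, is an unlikely source, since the list's median was -0.72 without that array. The scaling of the arrays is unlikely as well, with a median of -0.68 under the less favourable of 2 other scalings. Separate processing of the reference glucose arrays stays open. Mutant glucose against mutant ethanol, which does not use them, had 28 genes lower and 1 higher. Camera gave adjusted p = 0.0394 there (adjusted p = 0.900 with an estimated correlation), and fry gave adjusted p = 0.0954. That contrast compares growth conditions and not strains, so it cannot decide the question at any p. Whether the loss of SFP1 lowers these genes in glucose alone remains open, since their ethanol median was -0.163 (adjusted p = 0.000332) without reference ethanol array 2 and 0.214 without reference ethanol array 3.

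The stress list was lower in the mutant in ethanol and higher in glucose, a difference of 0.96 in its median (adjusted p = 0.326, 0.297 and 0.397 with an estimated correlation in ethanol, in glucose and for the difference). The scaling of the arrays is unlikely to produce it, with 0.93 under the less favourable scaling, and so is 1 array, with 0.82 as the smallest difference when each was left out. The ethanol median of -0.43 was -0.702 without reference ethanol array 3. Separate processing of the reference glucose arrays, which does not bear on the fall in ethanol, stays open for the rise in glucose. Mutant glucose against mutant ethanol had 13 genes higher and 4 lower. Camera gave adjusted p = 0.000845 there (adjusted p = 0.564 with an estimated correlation), and fry gave adjusted p = 0.089. A contrast of growth conditions within the mutant holds no strain difference, so it cannot decide the question. An effect of SFP1 loss that depends on the growth condition remains a hypothesis.

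Lists whose difference passed camera but not fry (mitochondrial ribosomal proteins, trehalose and glycogen, and the cell wall) are left out here. The other lists that passed both had median differences of -0.32 for RNA polymerase I and III genes, -0.54 for translation factors, -0.53 for aminoacyl-tRNA synthetases, -0.27 for the proteasome, 0.18 for glycolysis, 0.23 for the TCA cycle and 0.51 for the PAU family. None of these was called with an estimated correlation (adjusted p = 0.397 to 0.507). Without 1 array the median was -0.544 for RNA polymerase I and III (mutant ethanol array 3), -0.475 for the proteasome (reference glucose array 2), 0.278 for glycolysis (reference glucose array 3) and 0.064 for the TCA cycle (reference glucose array 2). Among genes that changed in ethanol, the effects of PTR2 (-2.93), PDR12 (-1.84), RAS1 (-1.80), RMD6 (-1.65), BAR1 (-1.20) and MFA1 (-0.80) were lower in glucose. Those of FMP45 (3.86), PMA2 (3.47), YGP1 (3.40), HPF1 (2.81), DSK2 (2.42), SPG1 (2.41), HEF3 (2.35), AQY1 (2.19) and LEU2 (1.40, or 1.72 with adjusted p = 0.0533 over the mean of its probe sets) were higher there. Among genes that fell in glucose, the difference was -2.26 for SNO1, -1.91 for RPA43, -1.35 for RPS9A, -1.35 for SNZ1 and -1.27 for HMT1. TKL2 (3.10), DIP5 (-2.74), YJL213W (-2.64) and ICY1 (-2.25) were among the largest differences. Outside the named genes, 79 of 897 probe sets without a gene name passed the test in glucose, 62 higher and 17 lower. That is a smaller share than the 718 of 5321 genes that passed there, so these probe sets show no excess.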

How the results depend on the processing

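Outside the repeats without 1 array, 798 results for single genes kept their direction and side of the threshold and 17 lost the call. For gene lists the numbers were 449 kept, 43 lost and 2 gained, and for counts, SFP1 and LEU2 161 kept and 17 moved. Stricter thresholds lower the counts by construction. At adjusted p under 0.01 the counts were 73 in ethanol, 285 in glucose, 94 for the difference, 1102 and 1019 for the condition in reference and mutant, and 14 shared. At 2-fold or more they were 102, 269, 338, 791 and 702, with 19 shared. On only the arrays compared they were 73 in ethanol, 448 in glucose, and 1446 and 1773 for the condition in reference and mutant, with 12 shared.

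With an estimated correlation 0, 1 and 0 lists were called in ethanol, glucose and the difference. Ribosome biogenesis was then not called at -0.730 in glucose (adjusted p = 0.295) and -0.713 for the difference (0.478), nor stress genes at -0.426, 0.396 and 0.955 (0.326, 0.297 and 0.397). Fry did not call the stress rise of 0.396 (0.053). These tests allow for genes that move together. After quantile normalization ribosomal proteins were called at 0.145 in ethanol (0.0388) and -0.231 for the difference (0.0127), and the cause was not tested.

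Without 1 array, the counts ranged over 72 to 291 in ethanol, 435 to 807 in glucose, 193 to 636 for the difference and 16 to 51 shared. Lists called in ethanol ranged over 3 to 9. Ribosome biogenesis in ethanol ran from -0.163 to 0.214 and turned its direction without reference array 3, and the cause was not tested. Ribosomal proteins ran from 0.049 to 0.267 in ethanol and from -0.265 to -0.020 for the difference. The ribosome biogenesis median stayed at -0.783 to -0.718 in glucose, and the stress median at -0.702 to -0.343 in ethanol and 0.314 to 0.434 in glucose. For single genes 833 results were kept and 7 lost, and for lists 403 were kept, 23 lost, 5 gained and 1 reversed.

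With the replicate number as a block the counts were 172, 683, 412, 1787 and 1660, with 34 shared. For the condition in the reference, where the numbers were taken to pair the arrays, the block on the 6 reference arrays alone gave 1464 calls against 1446 without it. In the fit of all arrays the block changed no camera call at the preset correlation and 0 of 127 named genes there, but 3 lists lost the call with an estimated correlation and 2 gained one by fry. Between the strains 5 of 6 arrays in ethanol and 0 of 6 in glucose correlated best with their own number, a hint from the data only. Genes on protein-coding transcripts alone, a choice made after seeing the data, gave 188, 637, 431, 1769 and 1610 calls. Signal near the floor limits what can be seen, since 26.48% to 32.64% of probe sets lay below it.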

Other observations

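The lists and genes in the next paragraph were chosen only after the data were seen, while the tests of chromosomes and of the SFP1 neighbourhood were set before.

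Permeases for nitrogen compounds changed in both directions in the mutant. Of 28 measured, PTR2 (3.39), DIP5 (1.54), GNP1 (1.44) and BAP2 (1.10) rose in ethanol, and MEP2 (-1.42), AGP3 (-1.34), DUR3 (-1.28), MEP1 (-1.15) and PUT4 (-0.97) fell. In glucose PUT4 (1.57), DUR3 (0.74) and DAL4 (0.59) rose, and MEP3 (-1.95), DIP5 (-1.21), MEP2 (-0.90) and SSY1 (-0.50) fell. Among 13 genes for vitamin B6 and thiamine 0 passed in ethanol. In glucose SNO1 (-2.53) and SNZ1 (-1.62) fell while THI21 (1.72), THI4 (0.98) and THI7 (0.78) rose.

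An extra or lost chromosome in the mutant strain would shift the genes of that chromosome the same way in both conditions. Over 16 chromosomes, the largest shift reached with the same sign in both conditions was 0.029 on the log2 scale, on chromosome XVI, which had -0.029 in ethanol and -0.072 in glucose. The largest in 1 condition was 0.155, so this explanation is unlikely. The marker inserted at SFP1 could change its neighbours. Of the 6 nearest genes measured (SKI2, BDF1, DUS3, SEI1, DUS4 and RPL31B), 0 were called the same way in both conditions. DUS3 rose in glucose by 0.92 (limma adjusted p = 0.0224), and in ethanol its change was 0.78 (adjusted p = 0.0887).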
